A study of Mus musculus with 6 samples.

How the data were processed

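RNA from PyMT mammary tumours of 3 SG-/- and 3 SG+/- mice was measured on Affymetrix whole-transcript arrays, 1 array per tumour. Tissue had been snap-frozen and RNA isolated with Trizol, per the labels. The deposited values are log2 expression values per probe set, made by the authors with the robust multi-array average (RMA), which corrects background, applies quantile normalization over probes and summarises each probe set. The submitters' processing notes name Affymetrix Expression Console, RMA and limma without versions. The 6 arrays held values for 33793 probe sets with 0 missing. Array medians ran from 6.50 to 6.73. The number of arrays limits the precision. The mice differ in every sample and nothing in the labels pairs them, so the groups were compared as independent.

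Probe sets were named from the platform's annotation table. There were 23521 with 1 gene symbol, 1814 with several and 8458 that the table did not hold. For the 1082 genes with more than 1 probe set, the one with the highest mean over the arrays was kept, which left 22180 genes. Of the probe sets with 1 symbol, 23328 had an Entrez ID in the RefSeq annotation of the mouse assembly GRCm38.p6, used only for names, synonyms and neighbouring genes.

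Genotypes were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, as SG-/- minus SG+/-, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Srgn also had an exact two-sided permutation test. Probe sets past an absolute log2 difference of 1.2 with an unadjusted p under 0.05 were counted, after the threshold in the series description, which gives no p-value rule. Gene lists were compared with the other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over 41 lists. Of 42 lists, 41 had at least 5 measured members, and 754 of 819 list entries matched a measured gene. The lists covered cell types of a mammary tumour sample, pathways linked to serglycin and metastasis, and technical classes such as olfactory and vomeronasal receptors. Members were also adjusted over the list alone. Similarity of arrays was described by Pearson correlations and principal components over all probe sets. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

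The comparisons, lists, alternatives and rule for named genes were fixed before the data were examined. The rule names Srgn. Because fewer than 10 genes passed, it then takes genes with an unadjusted p under 0.05, an absolute log2 difference of at least 1.2 and no overlap between genotypes, and names the 8 largest in each direction, leaving out predicted genes, receptors and small RNAs. For the 8 lists with the smallest camera p it names the member written first and the 2 members with the smallest limma p, and for other lists the member written first where an example is given.

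The test was run on simulated data with the same layout and 22180 genes. The simulated genes varied independently of each other, without the variation that the real arrays share across genes. The recovery therefore does not measure the power or error rate in the real data. It recovered 50 of 100 genes changed by 1 on the log2 scale and 90 of 100 changed by 2, and called 5 unchanged genes. A simulated list shifted by 0.5 gave a camera p of 1.12e-21 and an unshifted list 0.676, also with uncorrelated members.

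The alternatives were to leave out dim genes (mean under the 40th percentile of probe sets, 6.09), to apply quantile normalization again, to centre each array on the median of its brighter genes, to use eBayes with trend and robust settings, arrayWeights, the mean of all probe sets of a gene, all probe sets, treat against a 1.2-fold change, other thresholds, camera with an estimated correlation, fry, and to leave out each mouse in turn. A covariate, the mean of each array over 1394 olfactory and vomeronasal receptor genes, was added after the data were seen. No column of values was left out.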

Results

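Gene expression was measured on whole-transcript arrays in mammary tumours from 6 mice that carried the PyMT transgene, which encodes the polyoma virus middle T oncoprotein and drives mammary tumour formation. Of these tumours, 3 came from mice without serglycin (SG-/-) and 3 from heterozygous mice (SG+/-). Serglycin is a proteoglycan of secretory granules and is made by many blood cells and by some tumour cells. The comparison asks which genes differ in the tumours when serglycin is lost. Each array gave log2 expression values for 33793 probe sets, of which 23521 carried 1 gene symbol and stood for 22180 genes. The number of arrays, 3 per genotype, limits the precision of every difference. All differences are SG-/- minus SG+/- on the log2 scale. The series description states 672 altered genes past a log2 fold threshold of 1.2, with 6 higher and 666 lower in SG-/- tumours. Here, probe sets rather than genes were counted past that threshold. The larger side was the opposite one, with 34 probe sets higher in SG-/- tumours and 14 lower. Of these, 23 and 12 also had an unadjusted limma p under 0.05. With that p and without SG+/- replicate 3, the larger side turned, with 20 higher and 24 lower.

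The targeted gene, Srgn (Entrez 19073, probe set 17241409), was lower in all 3 SG-/- tumours than in any SG+/- tumour. Its level was 6.52 ± 0.22 in SG+/- tumours and 5.0 ± 0.10 in SG-/- tumours (SD, n = 3 each). The difference was -1.52 with a standard error of 0.15 and a 95% confidence interval from -1.88 to -1.16, which is 2.86-fold lower. Since the SG-/- values lie at the level of silent genes, this may understate the loss, but the floor of this probe set is not known. Srgn ranked 1 of 22180 genes by limma, with an adjusted p of 0.467. With the receptor mean of each array as a covariate, a setting chosen after the data were seen, the difference was -1.53 and passed (limma adjusted p = 0.0446), and over the 11 settings tried for Srgn the adjusted p ran from 0.0446 to 1.00. Leaving out dim genes removes Srgn, whose mean over the arrays lies under the dim level of 6.09. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 values allow. The SG-/- level lay within the range of array means, from 4.57 to 5.86, of 1394 olfactory and vomeronasal receptor genes taken to be silent in this tissue. Which part of the gene was removed, and where on the transcript the probe set lies, are not given in the sources used here. Of 28 measured genes that flank Srgn on its chromosome, 11 were higher in SG-/- tumours, and their median difference was -0.05.

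**Figure D1:**
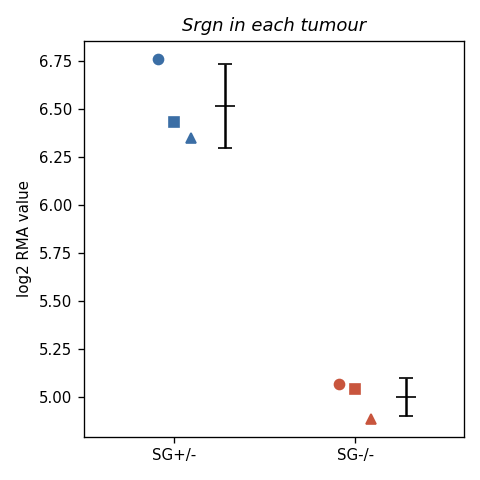
Level of Srgn in each tumour as a log2 RMA value (vertical axis), with SG+/- tumours in blue and SG-/- tumours in red. Bars give the mean and SD of 3 tumours, and the SG-/- values between 4.89 and 5.07 lie under the SG+/- values between 6.35 and 6.76.

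The arrays did not group by genotype over all probe sets. The mean Pearson correlation was 0.970 over the 6 pairs of arrays within a genotype and 0.975 over the 9 pairs between genotypes, across probe sets, which are not independent replicates. The highest correlation, 0.989, joined SG+/- replicate 1 and SG-/- replicate 1. The lowest, 0.941, lay between SG+/- replicate 1 and SG-/- replicate 3. The first principal component held 62.8% of the variance, and its values for the genotypes interleaved (exact permutation p = 0.9). Arrays also differed in their spread. The interquartile range was 3.15 in SG-/- replicate 1 and 2.56 in SG-/- replicate 3, and the mean of the 1394 receptor genes was 4.57 and 5.86 in these arrays.

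**Figure D2:**
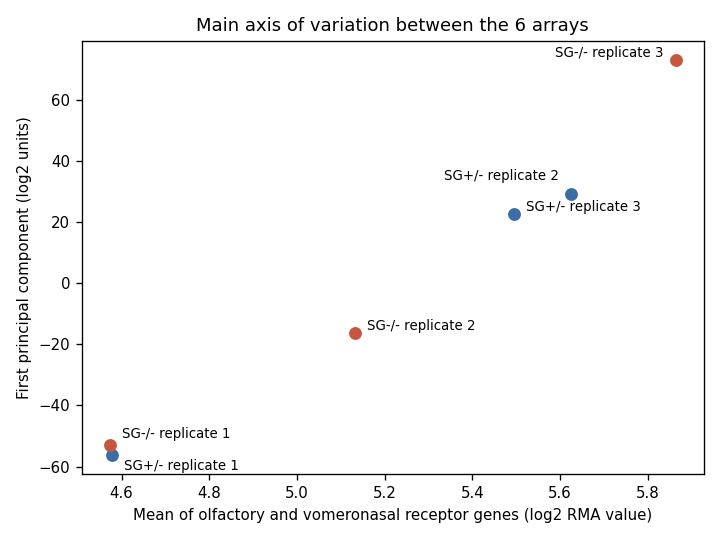
First principal component of all probe sets (vertical axis, log2 units) against the mean log2 RMA value of 1394 olfactory and vomeronasal receptor genes (horizontal axis) for the 6 arrays, with SG+/- in blue and SG-/- in red. The receptor means run from 4.57 in SG-/- replicate 1 to 5.86 in SG-/- replicate 3, and the genotypes interleave on both axes.

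Of the genes named by the rule (unadjusted p under 0.05, no overlap between genotypes, predicted genes, receptors and small RNAs left out), Bpifa2 and Klk1 had the largest differences toward higher expression in SG-/- tumours and Dcpp2 the largest toward lower. Bpifa2, which encodes the parotid secretory protein, was 5.27 higher with a standard error of 1.6, and Klk1, a tissue kallikrein, was 4.45 higher with a standard error of 0.82. The Klk1 level in SG+/- tumours and the Dmbt1 level in SG-/- tumours (5.44) lie near the level of silent genes. Their differences may thus be understated. Single tumours differed widely for both genes. Bpifa2 stood at 13.5, 7.26 and 13.6 in SG-/- replicates 1 to 3 against 6.21 ± 0.25 in SG+/- tumours (SD, n = 3), and Klk1 at 9.02, 10.4 and 6.74 against 4.27 ± 0.30. Pip, the prolactin-inducible protein, was 2.14 higher, and Scgb2b26, a secretoglobin, was 1.66 higher. Further genes on this side were Ogn, a small leucine-rich proteoglycan (1.46), Itprid1 (1.46), Cxcl13, a chemokine that attracts B cells (1.45), and R3hdml (1.42). On the lower side, Dcpp2, which encodes a demilune cell and parotid protein, differed by -2.54, A2m, a protease inhibitor, by -2.22, and Dmbt1, a mucosal scavenger receptor, by -1.99. Cpm, a carboxypeptidase, differed by -1.95, Chad, a matrix protein, by -1.57, Ceacam10 by -1.50 and Duoxa1, a maturation factor of dual oxidases, by -1.43. In each of these genes the values of the genotypes did not overlap, and none passed the adjustment over all genes (limma adjusted p = 1.00 for each). Klk1, Dcpp2, Scgb2b26 and Ceacam10 belong to families of similar genes, and whether their probes separate these relatives was not tested here, so the gene behind each signal is uncertain. Without SG-/- replicate 2, the Bpifa2 difference was 7.38 and passed (limma adjusted p = 4.9e-04), and with limma array weights it was 2.15 (adjusted p = 0.600). Other values also moved with single tumours. Without SG+/- replicate 1 Pip was 1.28 higher, without SG+/- replicate 2 Chad differed by -0.90 and Dcpp2 by -1.59, and without SG-/- replicate 1 Cxcl13 was 0.92, Ogn 0.94 and R3hdml 0.90 higher. With array weights Pip was 1.2 higher and Chad and Ceacam10 differed by -1.01 and -0.85.

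Over all genes, limma called 0 of 22180 at an adjusted p of 0.05, with a smallest adjusted p of 0.467. At an unadjusted p of 0.05 there were 469 genes, 317 higher and 152 lower in SG-/- tumours, while 1109 would pass by chance alone. This count was 1200 without SG-/- replicate 3, above the chance number, and 2569 with limma array weights. Those weights were estimated from the same values and were 4.95 for SG-/- replicate 2 and 0.20 for SG-/- replicate 3. The chance number takes no account of this, so 2569 cannot be set against it. The values of the genotypes did not overlap in 1338 genes, 630 higher and 708 lower in SG-/- tumours, 6.03% of those tested, against 10% by chance. At the stated threshold of 1.2 with an unadjusted p of 0.05, 35 of 33793 probe sets passed, and with no p-value rule 48 did, 34 higher and 14 lower. Read as a 1.2-fold change on the linear scale, the threshold with an unadjusted p of 0.05 gave 628 probe sets, 418 higher and 210 lower, the same count as that p alone. With no p-value rule the 1.2-fold threshold gave 4297, 2507 higher and 1790 lower. No reading that was tried gave a majority of lower probe sets over all 6 arrays. Without SG+/- replicate 3, 20 probe sets were higher and 24 lower. The count was 54 without SG-/- replicate 2, and without SG-/- replicate 3 it was 55.

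Of the 41 gene lists tested, 18 rose and 1 fell in SG-/- tumours by camera at an adjusted p of 0.05. With a correlation between genes estimated from the data, 0 lists passed, and the smallest adjusted p was 0.169. The fry test, which asks whether a list's genes move one way on balance, passed 0 lists, with a smallest adjusted p of 0.0631. In 6 of the 19 lists past camera the array medians of the genotypes did not overlap. These were interferon-stimulated genes, dendritic cell and MHC class II genes, chemokines, macrophages, T cells and inflammatory cytokines. Over all 41 lists the count was also 6, against 10% by chance. The gap was slight for T cells, with -0.0060 in the lowest SG-/- and -0.011 in the highest SG+/- array. It was slight for macrophages too, with 0.078 and 0.067, for chemokines, with 0.072 and 0.039, and for inflammatory cytokines, with 0.048 and 0.015.

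**Figure D3:**
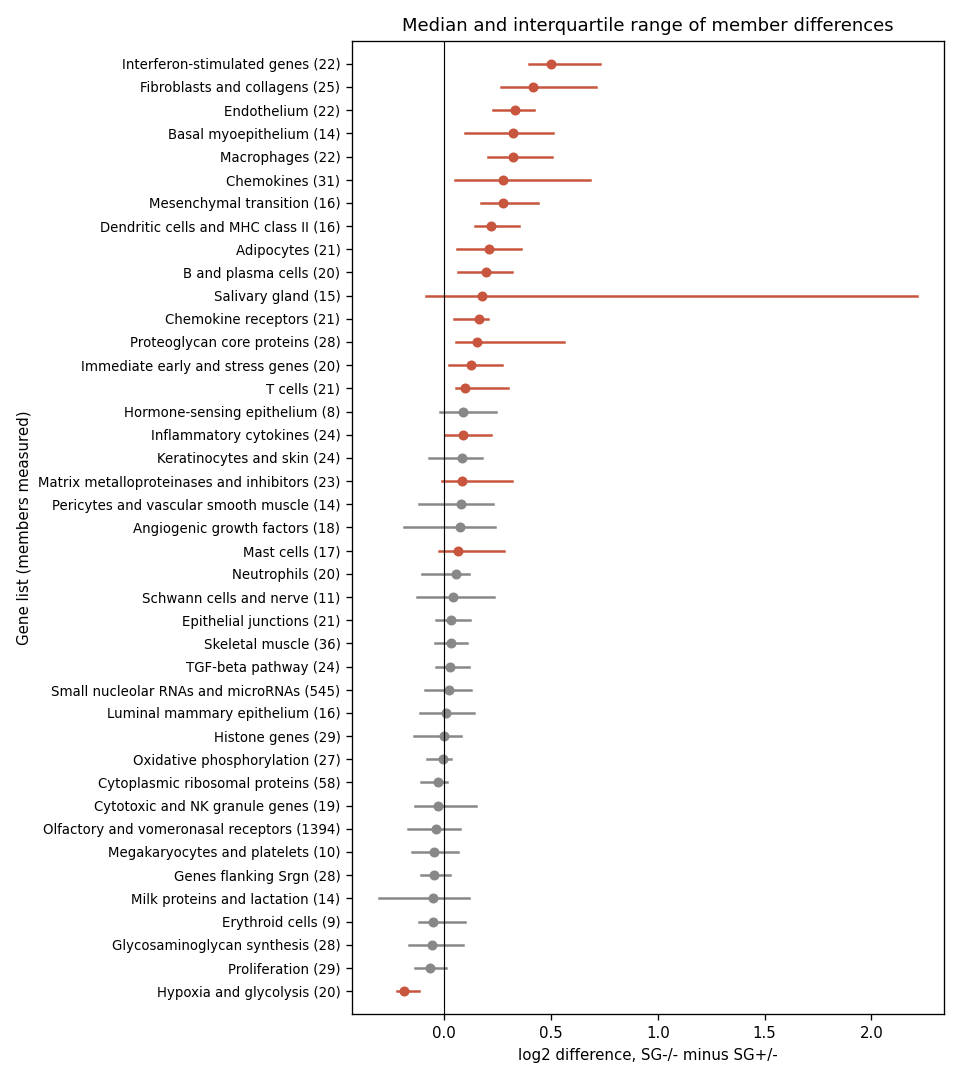
Median (point) and interquartile range (line) of the log2 difference, SG-/- minus SG+/-, over the measured members of each of 41 gene lists, with the number of members in brackets and lists past a camera adjusted p of 0.05 in red. The interferon-stimulated genes have the highest median, 0.50, and hypoxia and glycolysis the lowest, -0.19.

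Interferon-stimulated genes, which cells switch on in response to interferons, rose in SG-/- tumours (camera adjusted p = 1.79e-36). With an estimated correlation the adjusted p was 0.169. All 22 measured members were higher in SG-/- tumours, with a median difference of 0.50. Adjusted over the list alone, 16 of the 22 passed in limma, while 0 passed over all genes, and in 18 the genotypes did not overlap. Rsad2, which encodes the antiviral protein viperin, was 0.83 higher (standard error 0.15), from 8.57 ± 0.14 in SG+/- to 9.40 ± 0.19 in SG-/- tumours (SD, n = 3 each). Gbp3, an interferon-induced guanylate-binding protein, was 0.83 higher (standard error 0.13), from 7.50 ± 0.16 to 8.33 ± 0.07. The shift was present in each SG-/- array. The median over members, relative to the SG+/- mean, was 0.61, 0.47 and 0.50 in SG-/- replicates 1 to 3 and -0.07, -0.08 and 0.16 in SG+/- replicates 1 to 3. The number of members past the list-alone adjustment was 10 without SG+/- replicate 1, 10 without SG+/- replicate 2 and 8 without SG-/- replicate 1.

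**Figure D4:**
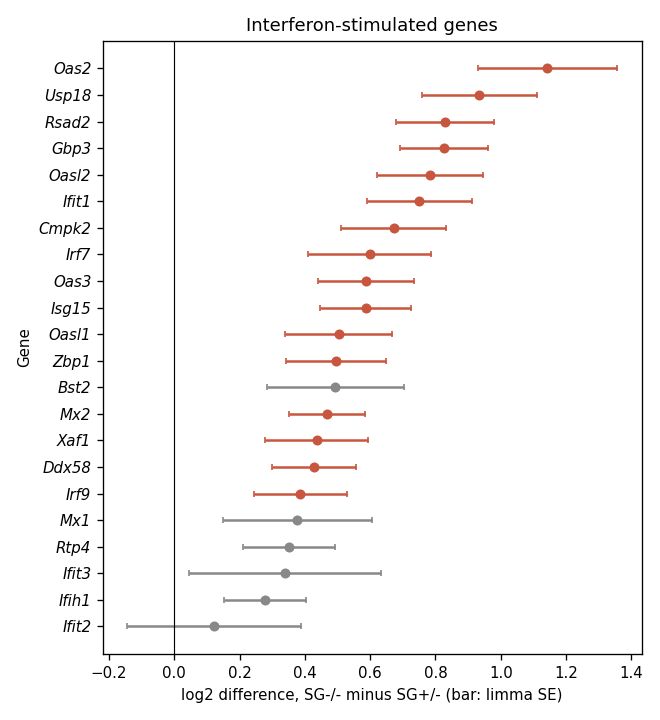
Log2 difference, SG-/- minus SG+/- (horizontal axis), of the 22 measured interferon-stimulated genes, with bars for the limma standard error and in red the 16 genes that pass when adjusted over the list alone. All 22 points lie above 0.

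The lists of endothelial markers, fibroblast and collagen genes, mesenchymal transition and proteoglycan core proteins rose, while pericytes and vascular smooth muscle did not pass (camera adjusted p = 0.486). Endothelial markers had a median difference of 0.33, with 20 of 22 members higher in SG-/- tumours (camera adjusted p = 4.79e-13). Array medians of the genotypes overlapped, at 0.55, 0.31 and 0.09 in SG-/- replicates 1 to 3 and up to 0.12 in SG+/- arrays. The adjusted p was 0.407 with an estimated correlation. Cdh5, the cadherin of endothelial junctions, was 0.51 higher, Vwf, the von Willebrand factor, 0.38 and Pecam1, an adhesion molecule of endothelium and platelets, 0.35. Fibroblast and collagen genes had a median difference of 0.41, with 23 of 25 members higher (camera adjusted p = 4.09e-11). Their adjusted p was 0.419 with an estimated correlation. Postn, a matrix protein, was 0.71 higher, Fap, a protease of activated fibroblasts, 0.59 and Col1a1 0.38. The fibroblast medians were 1.05, 0.07 and 0.10 in SG-/- replicates 1 to 3 and 0.11, 0.11 and -0.16 in SG+/- replicates 1 to 3. SG-/- replicates 2 and 3 thus lay under SG+/- replicates 1 and 2, and the rise rested on SG-/- replicate 1. Without SG-/- replicate 1 the fibroblast median was 0.09, Col1a1 differed by -0.03 and Pecam1 by 0.20, while Col1a1 was 0.81 higher without SG-/- replicate 2. With array weights the fibroblast median was 0.26. Genes of mesenchymal transition had a median difference of 0.27, with 15 of 16 higher (camera adjusted p = 7.32e-07). The adjusted p was 0.407 with an estimated correlation. The array medians were 0.56, 0.47 and -0.10 in SG-/- replicates 1 to 3, so that SG-/- replicate 3 lay below all SG+/- arrays. Among the members S100a4 was 0.63 higher, Tgfbi 0.54 and Vim 0.26, and the median was 0.49 without SG-/- replicate 3 and 0.48 with array weights. Vim was 0.13 higher without SG+/- replicate 1, 0.11 without SG-/- replicate 2, 0.42 without SG+/- replicate 2 and 0.47 without SG-/- replicate 3. With array weights Vim was 0.52 higher. Proteoglycan core proteins had a median difference of 0.15, with 23 of 28 higher (camera adjusted p = 7.32e-07). The adjusted p was again 0.407 with an estimated correlation. The small leucine-rich proteoglycans Fmod and Prelp were 1.06 and 0.89 higher and Vcan differed by -0.01. The list median was 0.07 without SG-/- replicate 1, 0.05 without SG-/- replicate 2, 0.35 without SG-/- replicate 3 and 0.26 without SG+/- replicate 2. With array weights the list median was 0.28. With the mean of all probe sets of a gene, Fmod was 0.71 and Prelp 0.45 higher. No member of these 4 lists passed the adjustment, over all genes or over its list alone (0 of 91 tests in limma).

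Among the immune lists that rose by camera were dendritic cell and MHC class II genes, chemokines, macrophages and T cells. Neutrophils (camera adjusted p = 0.641) and cytotoxic and NK granule genes (camera adjusted p = 0.58) did not pass. Dendritic cell and MHC class II genes had a median difference of 0.22, with 15 of 16 members higher in SG-/- tumours (camera adjusted p = 4.96e-09). With an estimated correlation their adjusted p was 0.187. H2-Eb1 and H2-Aa, which encode class II chains that present antigen, were 0.92 and 0.79 higher, and Itgax, an integrin of dendritic cells, 0.14. H2-Eb1 alone passed when adjusted over the list alone (limma adjusted p = 0.0491). Only 4 members, H2-Eb1, H2-Aa, H2-Ab1 and Irf8, had an unadjusted limma p under 0.05. Among the other members, Flt3 and Zbtb46 were 0.23 higher, Xcr1 0.21 and Cd209a 0.02, and Batf3 differed by -0.12. The list's shift can thus not be read as more dendritic cells. Chemokines had a median difference of 0.28, with 24 of 31 members higher (camera adjusted p = 2.43e-08). Their adjusted p was 0.292 with an estimated correlation. The chemokine medians were 0.47, 0.07 and 0.18 in SG-/- replicates 1 to 3. No member of the chemokine, macrophage or T cell lists passed in limma when adjusted over its list alone. Cxcl9, which is induced by interferon gamma and attracts T cells, was 1.24 higher, Ccl2, which attracts monocytes, 1.00 and Ccl5 0.75. Macrophage markers had a median difference of 0.32, with 20 of 22 higher (camera adjusted p = 6.45e-08). Their adjusted p was 0.407 with an estimated correlation. The Fc receptor gene Fcgr1 was 0.65 higher and Adgre1, which encodes F4/80, 0.53. With SG-/- replicate 1 left out, Ccl2 was 0.56, Fcgr1 0.41, Adgre1 0.31 and Itgax 0.050 higher, and Itgax was 0.26 higher without SG-/- replicate 3. The macrophage medians were 0.74, 0.29 and 0.08 in SG-/- replicates 1 to 3, and the median difference was 0.11 without SG-/- replicate 1 and 0.49 without SG-/- replicate 3. T cell markers had a median difference of 0.10, with 19 of 21 higher (camera adjusted p = 4.56e-06). The adjusted p was 0.375 with an estimated correlation. Cd3e, a chain of the T cell receptor complex, was 0.44 higher. The T cell median was 0.18 without SG+/- replicate 2, 0.17 without SG+/- replicate 3 and 0.21 without SG-/- replicate 2, and with limma array weights it was 0.02 and did not pass (camera adjusted p = 0.164).

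Hypoxia and glycolysis genes fell, with 18 of 20 measured members lower in SG-/- tumours and a median difference of -0.19 (camera adjusted p = 3.51e-04). With an estimated correlation it did not pass (adjusted p = 0.440). Vegfa, a growth factor for vessels, differed by -0.36. The array medians were -0.17, -0.0094 and -0.32 in SG-/- replicates 1 to 3 and between -0.045 and 0.067 in SG+/- arrays. Without SG-/- replicate 3 the median was -0.10 and the list did not pass (camera adjusted p = 0.190), nor did it with array weights, where the median was -0.029 (camera adjusted p = 0.756).

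The other lists past camera each lost the call when certain single arrays were left out. Chemokine receptors had a median difference of 0.16 (camera adjusted p = 1.57e-04, or 0.407 with an estimated correlation as adjusted p) and did not pass without SG-/- replicate 3 (median 0.090, adjusted p = 0.111). B and plasma cell markers had a median of 0.20 (camera adjusted p = 3.76e-04, with an estimated correlation adjusted p = 0.623). This median was 0.49 in SG-/- replicate 3 and between -0.07 and 0.04 in the other SG-/- arrays, and without that array the difference was 0.02. The receptor genes taken as silent also rose in SG-/- replicate 3, with a median of 0.60, and only 55% of B cell members lay above the dim level. The median difference was still 0.22 with dim genes left out and 0.21 with the receptor mean as a covariate, a setting chosen after the data were seen. Whether the rise in that array is particular to B cells was thus not settled. Adipocyte markers had a median of 0.21 (camera adjusted p = 6.13e-04, with an estimated correlation adjusted p = 0.481) and did not pass without SG+/- replicate 2 (median 0.12, adjusted p = 0.173) or SG-/- replicate 3 (median 0.11, adjusted p = 0.105). Salivary gland genes had a median of 0.18 and a mean of 1.06 over 15 members (camera adjusted p = 0.00182, with an estimated correlation adjusted p = 0.419). They did not pass without SG+/- replicate 1 (median 0.21, adjusted p = 0.0634) or SG-/- replicate 3 (median 0.045, adjusted p = 0.163), and Klk1 passed when adjusted over the list alone (limma adjusted p = 0.0149). Inflammatory cytokines had a median of 0.09 (camera adjusted p = 0.00909, with an estimated correlation adjusted p = 0.320) and did not pass without SG+/- replicate 3 (median 0.085, adjusted p = 0.0568) or SG-/- replicate 3 (median 0.054, adjusted p = 0.0560). Basal myoepithelial markers had a median of 0.32 (camera adjusted p = 0.0127, with an estimated correlation adjusted p = 0.710). The difference was 0.01 without SG-/- replicate 2, where the median stood at 1.03, and the list did not pass without SG+/- replicate 1 (median 0.20, adjusted p = 0.0929) or SG+/- replicate 3 (median 0.31, adjusted p = 0.0568). Matrix metalloproteinases and their inhibitors had a median of 0.08 (camera adjusted p = 0.0158, with an estimated correlation adjusted p = 0.407) and did not pass without SG+/- replicate 3 (median 0.091, adjusted p = 0.247) or SG-/- replicate 1 (median 0.080, adjusted p = 0.294). Mast cell markers had a median of 0.07 (camera adjusted p = 0.0158, with an estimated correlation adjusted p = 0.623) and did not pass without SG+/- replicate 1 (median 0.019, adjusted p = 0.127) or SG-/- replicate 3 (median -0.022, adjusted p = 0.835). Immediate early and stress genes had a median of 0.13 (camera adjusted p = 0.0258, with an estimated correlation adjusted p = 0.821), which was -0.05 without SG-/- replicate 1, and they did not pass without SG+/- replicate 3 (median 0.12, adjusted p = 0.326). Without SG-/- replicate 2 the median was 0.68 for salivary gland genes, 0.14 for inflammatory cytokines, 0.13 for metalloproteinases and 0.18 for mast cells. Without SG-/- replicate 3 it was 0.56 for basal myoepithelium and 0.26 for immediate early genes. Without SG+/- replicate 2 it was 0.34 for salivary gland genes and 0.12 for mast cells, and without SG+/- replicate 3 it was 0.28 and 0.13. With array weights, 7 of these 9 lists did not pass: chemokine receptors (median 0.010), B and plasma cells (-0.038), adipocytes (-0.023), salivary gland genes (-0.14), inflammatory cytokines (0.051), metalloproteinases (0.066) and mast cells (-0.17), while basal myoepithelium had a median of 0.75.

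**Figure D5:**
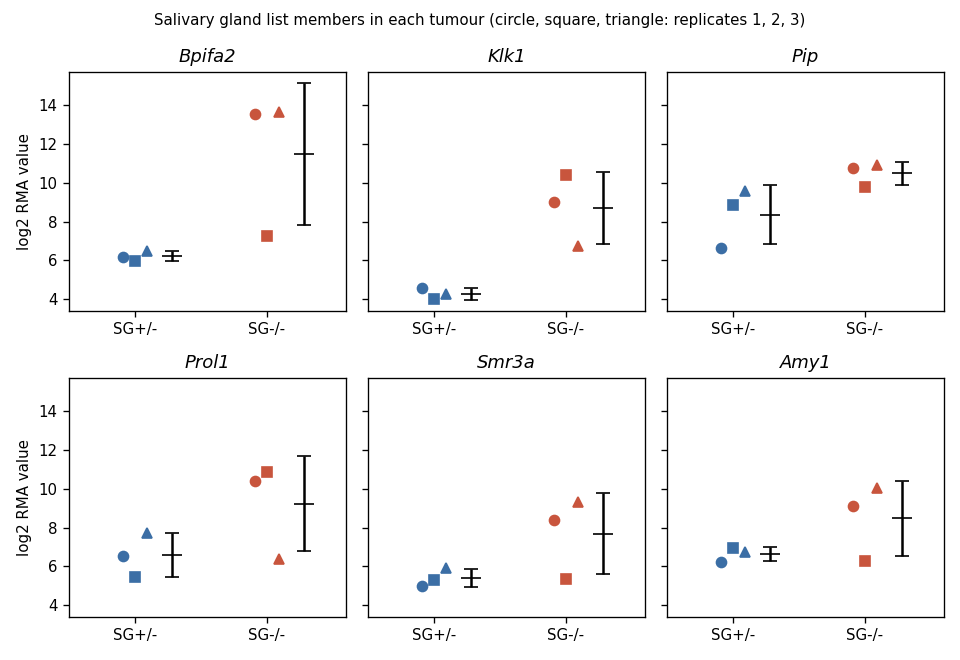
Level of 6 salivary gland list members in each tumour as log2 RMA values (vertical axes), with SG+/- tumours in blue, SG-/- tumours in red, and the mean and SD of 3 tumours beside them. Bpifa2 stands at 13.5, 7.26 and 13.6 and Klk1 at 9.02, 10.4 and 6.74 in SG-/- replicates 1 to 3.

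The remaining 22 lists did not pass camera. Among tumour cell genes, the median difference was -0.07 for proliferation, 0.01 for luminal epithelium, 0.09 for hormone-sensing epithelium, -0.05 for milk proteins and 0.03 for epithelial junctions. Keratinocyte markers had a median of 0.09, neutrophils 0.06, cytotoxic and NK granule genes -0.03, platelets -0.05, erythroid cells -0.05, pericytes and vascular smooth muscle 0.08, skeletal muscle 0.03 and Schwann cells 0.04. The median was 0.07 for angiogenic growth factors, 0.03 for the TGF-beta pathway and -0.06 for glycosaminoglycan synthesis. It was -0.01 for oxidative phosphorylation, -0.03 for ribosomal proteins, 0.02 for small nucleolar RNAs and microRNAs, -0.04 for the receptor genes taken as silent and -0.0023 for histone genes, with the genes flanking Srgn as given above. For hormone-sensing epithelium the median was positive and the mean, -0.0045, was negative. For cytotoxic and NK granule genes the median and mean were negative while the test pointed up.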

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

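The receptor-mean covariate was the alternative chosen after the data were seen. Srgn kept its direction under its 11 alternatives, from -1.60 to -1.39, with an adjusted p from 0.0446 to 1.00; it passed with the covariate, at -1.53 with an adjusted p of 0.0446, and was then the 1 gene called. By limma, 0 genes passed under the other adjusted settings, except 1 without SG-/- replicate 2 (0 to 1 over the single mice left out), and 469 at an unadjusted p of 0.05. The self-test made calls at this number of arrays, but its genes were simulated as independent, so it does not show the power in these data. The cause of these changes was not tested. Dim genes limit what can be seen: Srgn itself had no value with them left out, only 17.6% of mast cell list members and 35% of neutrophil list members lay above 6.09, and the mast cell list had too few members for a value with dim genes left out.

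The count of 35 probe sets past the stated threshold was 78 with arrayWeights (58 higher, 20 lower), 628 for a 1.2-fold change (418 higher, 210 lower) and 0 with an adjusted p. It ran from 27 to 55 when 1 mouse was left out, with 54 without SG-/- replicate 2 and 55 without SG-/- replicate 3, and the larger side turned without SG+/- replicate 3, with 20 higher and 24 lower. ArrayWeights gave SG-/- replicate 3 a weight of 0.20 and SG-/- replicate 2 a weight of 5.22 in that fit. The cause was otherwise not tested.

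The 19 gene list calls became 0 with an estimated correlation and 0 with fry. These tests leave the medians as they were, at 0.50 for interferon-stimulated genes, 0.33 for endothelium, 0.41 for fibroblasts and collagens, 0.22 for dendritic cells, 0.28 for chemokines, 0.32 for macrophages, 0.27 for mesenchymal transition and 0.15 for proteoglycans. The estimated correlation, 0.229 for interferon-stimulated genes against the preset 0.01, widens the error of a list's mean. Under the other alternatives these 8 lists kept their direction and their call. The 16 interferon-stimulated genes past the adjustment over the list alone numbered 8 to 17 when 1 mouse was left out, with 10 without SG+/- replicate 1, 10 without SG+/- replicate 2 and 8 without SG-/- replicate 1.

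Directions turned in these cases, and the cause was not tested. With arrayWeights Col1a1 was -0.091, Vcan 0.29, B and plasma cells -0.038, mast cells -0.17, adipocytes -0.023 and salivary gland genes -0.14. With 1 mouse left out, Col1a1 ran from -0.027 to 0.81, Vcan from -0.31 to 0.34, mast cells from -0.022 to 0.18 and immediate early genes from -0.047 to 0.26. The test, not the median, turned for basal myoepithelium, whose median ran from 0.0093 to 0.56 (lowest without SG-/- replicate 2), and for B and plasma cells, from 0.018 to 0.27 (lowest without SG-/- replicate 3). For named genes, 485 alternative values kept direction and side of the threshold. For the 19 lists past camera, 181 did, 60 lost the call and 5 reversed.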

Other observations

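The tests weighed here, and the genes named in these paragraphs, were chosen after the results were seen.

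Some interferon-regulated genes outside the fixed list, picked after their values were seen, had higher values in SG-/- tumours. The GTPase genes Iigp1, Igtp and Irgm2, which act against pathogens inside cells, were 0.91, 0.67 and 0.51 higher, and Ddx60, Trim30a and Herc6 were 0.93, 0.92 and 0.62 higher. In each of these 6 genes all SG-/- values lay above all SG+/- values, and none passed the limma adjustment over all genes (adjusted p = 1.00). Among genes that monocytes express, Ly6c2 was 1.31, Clec7a 1.2, Plac8 1.16 and Ccr2 0.86 higher, and none of these 4 passed either (adjusted p = 1.00). Ccr2 stood at 8.55, 7.45 and 7.68 in SG-/- replicates 1 to 3 against a mean of 7.04 in SG+/- tumours, so replicate 1 carried much of its difference. In the same replicates Ly6c2 stood at 8.05, 7.35 and 6.46, Clec7a at 9.10, 8.69 and 7.79, and Plac8 at 7.67, 7.19 and 6.65. The Ly6c2 value of SG-/- replicate 3 lay close to that of SG+/- replicate 1, 6.43. No list of monocyte genes was tested. On the lower side, Scube1 stood at 9.70 ± 0.34 in SG+/- and 8.33 ± 0.24 in SG-/- tumours (SD, n = 3 each), a difference of -1.37. The neurotrophin receptor gene Ntrk2 differed by -1.07 and Lgr5, a stem cell receptor gene, by -0.87, and none of these 3 passed (limma adjusted p = 1.00).

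Some genes stood out in single tumours. The granzyme genes Gzmd, Gzmf and Gzmg stood at 6.95, 7.02 and 6.20 in SG+/- replicate 2 and between 3.80 and 4.87 in the other arrays. Whether their probes separate these related genes was not tested, so they may not be separate signals. The B cell genes Ms4a1 and Cd79a stood at 6.43 and 6.35 in SG-/- replicate 3 and between 4.60 and 5.55 in the other arrays. The mean of the receptor genes taken as silent was also highest in SG-/- replicate 3, at 5.86. Whether this accounts for the B cell values was not tested. Dcpp3 stood at 12.2 in SG+/- replicate 2 and between 7.23 and 10.3 in the other arrays.

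The rise of interferon-stimulated genes was weighed against 3 explanations. Receptor means ranged by 1.29 within SG-/- and 1.05 within SG+/- arrays while the list median ranged by at most 0.238, under the difference of 0.50 between genotypes, which argues against an array-wide shift of the kind the receptor mean measures. More macrophages, fibroblasts or endothelium stays open: the interferon list was 0.47 or more in each SG-/- array, and these lists reached at most 0.308 in their middle SG-/- array and 0.0911 in their lowest. More lymphoid or dendritic cells stays open too: the dendritic list reached 0.156 in its lowest SG-/- array, and only 42.1% of cytotoxic and 55% of B cell members lay above the dim level. An interferon response tied to the genotype may also account for it, and differences between mice that the labels do not give were not tested.

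Of 15 salivary gland genes 10 were higher in SG-/- tumours, with a median of 0.18 (-0.14 with array weights; adjusted p = 0.419 with an estimated correlation), while Dcpp2 differed by -2.54 and Dcpp3 was highest in SG+/- replicate 2, at 12.2. A single salivary tissue of fixed makeup in all 3 samples is argued against by the difference of Klk1 and Bpifa2, which was -4.52, 3.14 and -6.90 in SG-/- replicates 1 to 3, a range of 10.04 on the log2 scale. Pieces of different salivary glands in different samples may be present, and this stays open: 7, 2 and 6 of 15 members were at least 1 above the highest SG+/- array, with a lowest count of 2. This count cannot settle it. Dcpp2 and Dcpp3 stood at 10.7 and 12.2 in SG+/- replicate 2, which sets a high mark for them, and SG+/- arrays were not scored. Prol1 was 10.9 and Amy1 6.29 in SG-/- replicate 2. Expression of these genes by the tumour cells themselves, tied to genotype or not, was not tested.

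The first principal component followed the mean of the olfactory and vomeronasal receptor genes. Computed without their 1405 probe sets, it held 59.0% of the variance and correlated with that mean at r = 0.972 (exact permutation p = 0.00278) and rho = 0.943 (exact permutation p = 0.0167) over 6 arrays, with r = 0.973 without the 2 farthest arrays, in the 1 relation computed. These genes are taken as silent in this tissue, so an array-wide technical shift of values is a candidate explanation. The values of the genotypes interleave on the component (exact permutation p = 0.9), which argues against genotype as the source of most of it. RNA quality per sample was not used here, and no biological explanation beyond genotype was tested.

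The 6 arrays can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split gave 0 genes in limma (469 at an unadjusted p of 0.05) and the highest other split gave 570; a real count of 0 makes this comparison empty. The split with 570 sets SG+/- replicate 1 with SG-/- replicates 1 and 2, the arrays with the 3 lowest values of the first principal component, and so points to a structure of the samples other than genotype. For probe sets past the stated threshold, the real split gave 35 and the highest other 1179, and 5 of the 10 splits gave as many. For gene lists past camera, the real split gave 19, the lowest other 3 and the highest other 26, and 3 splits gave as many. For the interferon-stimulated genes, the real split had a median of 0.50 and the highest other 0.34, and 1 split, the real one, was as large. With SG+/- replicates 1 and 2 and SG-/- replicate 2 as 1 group, camera gave this list an unadjusted p of 7.11e-07. Every other split shares the genotypes unequally between its groups, so part of any genotype difference remains in it. This p can therefore not show whether a small camera p for this list arises without genotype.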
